A study of Mus musculus with 4 samples.

How the data were processed

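The study measured RNA in 4 libraries of mouse bone marrow neutrophils, 2 treated with vehicle and 2 with ruxolitinib. Per the labels' protocols, RNA was extracted with Trizol and libraries followed standard Illumina protocols. The treatment was assigned from each sample's treatment label. The replicate number came from the sample titles. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used with the build GRCm38.p6, with no versions stated, and the annotation is not given in the sources used here.

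Each deposited file held 16566 genes with an Entrez identifier and a symbol. Per the file headers, the authors deposited for each gene a read count, which the values show to be an estimated count, as RSEM gives, of which 91.0% to 91.1% were whole within 1e-06. Per the file headers, the deposited files also held a TPM and an FPKM value for each gene, scaled by the authors to library size and gene length. The TPM and FPKM values were used to compare library properties and to derive gene length, never for a test. The median ratio of TPM to FPKM was 1.46 in ruxolitinib replicate 2 and between 1.71 and 1.73 in the other libraries. Of the identifiers, 16466 matched the RefSeq gene table of GRCm38.p6, the build the submitters name, and coordinates come from that table, counted from 1. Of the matched genes 16289 are protein coding. No mitochondrially encoded gene was in the files, so that list could not be measured.

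Estimated counts were rounded to whole numbers. Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr at its defaults (a count of about 10 in enough libraries and 15 in total), which left 11611. Library sizes were scaled by TMM, and CPM values are edgeR's cpm on the scaled library sizes. Ruxolitinib was compared with vehicle by edgeR's quasi-likelihood test, with group as the only term and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so none was run. The rounded total counts set the counting error, which is small beside the spread between libraries: the common BCV was 25.7%.

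Gene lists were written from general knowledge before the data were examined: pathways and neutrophil functions, markers of other marrow cells, and ribosomal protein genes. Lists were tested with limma's camera on log2 CPM (prior count 2, inter-gene correlation 0.01), beside camera with an estimated correlation and fry, with adjustment over the 25 lists tested. Of the 6 lists that camera called at the preset correlation, 0 held with an estimated correlation, and fry called 0 lists for a shared direction and 0 for change in either direction. With an estimated correlation the smallest unadjusted camera p was 0.158, for the eosinophil, basophil and mast cell markers. The adjustment gave many lists the same adjusted p of 0.80, so this value is not separate evidence against each list. Medians of lists in single pairs of libraries were set against 10000 random lists of the same size matched on abundance in 20 bins. Members of a list can vary together, which random lists do not reproduce, so these percentiles are not p-values.

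Genes were named by a rule fixed before the data were examined. With fewer than 3 genes past the threshold, it took the 5 smallest unadjusted p-values in each direction among genes at or above the median abundance whose groups do not overlap, leaving out predicted genes, Rik clones and pseudogenes. It added up to 4 members of each list with the smallest p-values, the 2 most abundant members of each list of other cells or RNA quality, and a set of JAK, STAT and feedback genes. The text gives a selection of the list members, and of the JAK, STAT and feedback set 1 gene is not reported here. Pairs of libraries were compared by the common BCV of the pair and by a chi-square test per gene with at least 20 counts in the pair.

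The procedures were tested on simulated data before use. In 5 simulated tables of 11611 genes with the fitted means, library sizes and dispersions, 200 genes were changed by 2-fold or 4-fold. The test called 82.9% of the 4-fold and 11% of the 2-fold genes, with 8.2 false calls per table on average, and 98.9% of changed genes had the right sign. Camera called a planted list in 5 of 5 tables and 0 of 120 unchanged lists. Simulated genes varied independently, whereas the lists called in the data had estimated correlations of 0.16 to 0.96. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. A simulated pair that differed by counting noise alone had a BCV of 0.0123%.

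Alternatives fixed before the data were examined were RLE scaling, DESeq2's Wald test (with camera on its statistics for the lists), limma-voom, a filter of 1 count in any library, a filter of 50 counts in 2 libraries, a prior count of 0.125, leaving out each library, the replicate number as a block, an estimated inter-gene correlation, a fold change of at least 2, and an adjusted p below 0.1. Removing each library's trend on gene length was added after the data were seen; effective length was derived from the ratio of count to FPKM, which was available for 89.7% of tested genes. No sample was left out.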

Results

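Gene expression was measured by RNA sequencing in neutrophils, the short-lived granule-bearing phagocytes, taken from the bone marrow of C57BL/6 mice at a stated purity above 95%. The cells were kept for 1 h in medium with 20% fetal bovine serum. They received either ruxolitinib, an inhibitor of the cytokine-receptor kinases JAK1 and JAK2, or its vehicle, a mixture of 80% glucose and 20% PEG300, for 1 h. The labels give the ruxolitinib concentration as 0.1 µM in one field and 1 µM in others, so the dose is uncertain. Each group held 2 libraries, and nothing states that they came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The libraries held 15419579 (vehicle replicate 1), 15096035 (vehicle replicate 2), 14954523 (ruxolitinib replicate 1) and 14235511 (ruxolitinib replicate 2) estimated counts, and between 14375 and 14575 genes had at least 1 count. The genes for neutrophil granule and calcium-binding proteins led all libraries: Ngp averaged 31652 ± 2204 counts scaled to library size (CPM; SD, n = 4), S100a9 20097 ± 3176 CPM and Ltf, which encodes lactoferrin, 12308 ± 857 CPM.

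The comparison of ruxolitinib with vehicle asks which transcripts of neutrophils respond to JAK inhibition within 1 h. No gene passed the threshold in either direction. Among the genes named by the fixed rule, the smallest p belonged to Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477274, GRCm38.p6), at 79.1 and 1214 CPM with vehicle and 72.9 and 49.9 CPM with ruxolitinib. Among the feedback targets of STAT proteins, Socs3, which encodes an inhibitor of JAK signalling, was at 63.9 and 147 CPM with vehicle and at 54.3 and 66.2 CPM with ruxolitinib, and Cish, another such inhibitor, was at 7.11 and 7.76 CPM against 7.57 and 8.24 CPM. Vehicle replicate 2 differed from vehicle replicate 1 by a median log2 of 0.44 over the immediate early genes and of -0.80 over the NF-kB targets.

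Of 11611 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower with ruxolitinib at an adjusted p below 0.05, and the smallest adjusted p was 0.975. At an unadjusted p below 0.05 there were 225 genes, 65 higher and 160 lower, where chance alone would give 580.55. DESeq2 and limma-voom also called 0 genes in either direction, with 232 and 188 genes at an unadjusted p below 0.05. The libraries of one group lay wholly above those of the other for 3166 genes (27.3%), where chance gives 33.3%. The call count rested on single libraries: without vehicle replicate 1 there were 853 genes higher and 792 lower, without vehicle replicate 2 there were 1 and 1, without ruxolitinib replicate 1 there were 4 and 6, and without ruxolitinib replicate 2 there were 1 and 5. Of the 96 genes that the naming rule selects, 55 passed without vehicle replicate 1, 0 without vehicle replicate 2, 4 without ruxolitinib replicate 1 and 3 without ruxolitinib replicate 2. In a simulation over the same 11611 genes, the test called 82.9% of genes changed 4-fold and 11% of genes changed 2-fold. Most changes of 2-fold or less were thus not detectable with this spread. Simulated genes varied independently, whereas here single libraries differed from the others over many genes. Fos, with a fitted log2 fold change of -3.40, was not called. The simulated share therefore does not show that changes of 4-fold would mostly have been called in these data.

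The spread between libraries did not follow the treatment. Vehicle replicate 1 and ruxolitinib replicate 1 were the closest pair, with a biological coefficient of variation (BCV, the spread beyond counting noise) of 3.63% and a Pearson correlation across genes of 0.995. The vehicle libraries differed from each other with a BCV of 31.7%, and the ruxolitinib libraries with a BCV of 17.7%. Between vehicle replicate 1 and ruxolitinib replicate 1, 591 of 11544 genes with at least 20 counts in the pair differed beyond counting noise (chi-square, Benjamini-Hochberg), 20 of them by 2-fold or more. Between the vehicle libraries, 7383 of 11684 such genes differed, 1627 of them by 2-fold or more. The chi-square values compare libraries, not treatments.

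**Figure D1:**
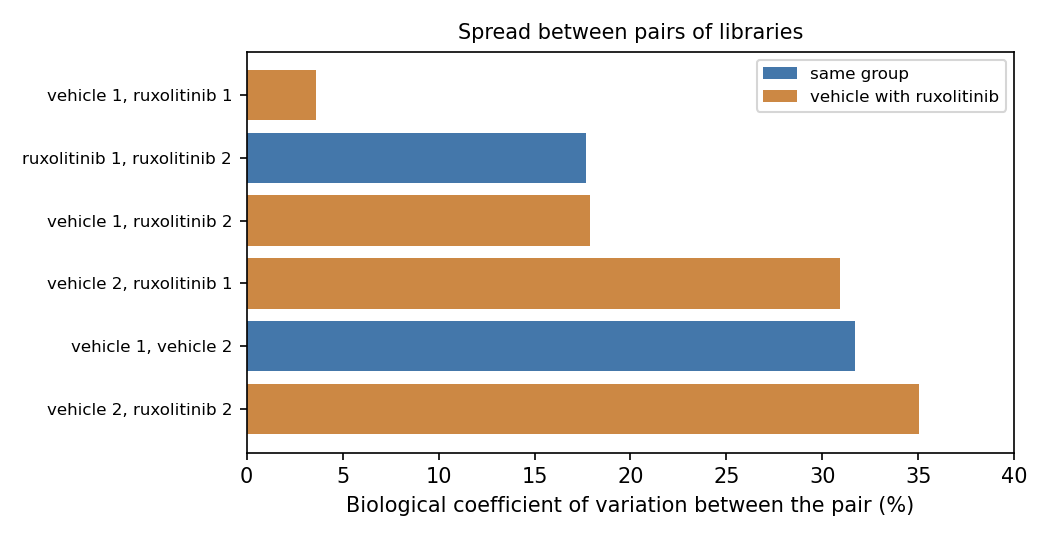
Biological coefficient of variation (percent, horizontal axis from 0) between each pair of libraries; blue bars are pairs within a group and orange bars pairs of a vehicle with a ruxolitinib library. The shortest bar, 3.63%, joins vehicle 1 with ruxolitinib 1, and the longest, 35.0%, joins vehicle 2 with ruxolitinib 2.

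Among the JAK-STAT target and feedback genes, 0 of 40 tested members passed the threshold, adjusted over all genes or adjusted over the list alone. The median log2 fold change of the list was -0.12, and camera did not call the list (adjusted p = 0.374, and 0.80 with an estimated correlation, at which no list was called). Osm, which encodes the cytokine oncostatin M, was at 63.0 and 226 CPM with vehicle and at 56.3 and 55.5 CPM with ruxolitinib, a log2 fold change of -1.37 ± 0.47 (SE, n = 2 per group; edgeR adjusted p = 0.975). Gadd45g, a stress-responsive gene, had a log2 fold change of -1.15 ± 0.40, and Socs3 one of -0.81 ± 0.38. Socs1, a further JAK inhibitor, was at 7.37 and 19.4 CPM with vehicle and 7.31 and 9.93 CPM with ruxolitinib. For Cish the log2 fold change was 0.09 with a 95% interval of -0.64 to 0.82, and for the survival kinase gene Pim1 it was -0.13 with an interval of -0.78 to 0.53. Bcl3, which encodes a partner of NF-kB subunits, was at 158 and 36.6 CPM with vehicle and 144 and 123 CPM with ruxolitinib. Socs2 stayed below 3 CPM in every library. Without vehicle replicate 2 the median of the list was 0.02, and without vehicle replicate 1, a fit in which a lone vehicle library is assumed to vary like the ruxolitinib libraries, 4 members were higher and 9 lower.

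The 29 tested JAK kinases, STATs and the receptors they serve held 0 calls, with a median log2 fold change of -0.08 (camera adjusted p = 0.763). Jak1 and Jak2, which encode the kinases that ruxolitinib binds, had log2 fold changes of 0.06 ± 0.26 and -0.15 ± 0.27 (SE, n = 2 per group). Jak3 was at -0.33 ± 0.32 and Tyk2 at -0.43 ± 0.30. Stat3 had a log2 fold change of 0.24 ± 0.30, Stat5a one of 0.00 ± 0.28 and Stat5b one of -0.31 ± 0.30. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 1715 and 2789 CPM with vehicle and 1758 and 1603 CPM with ruxolitinib. Il10ra, a receptor chain for interleukin 10, had a log2 fold change of 0.87 ± 0.35.

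**Figure D2:**
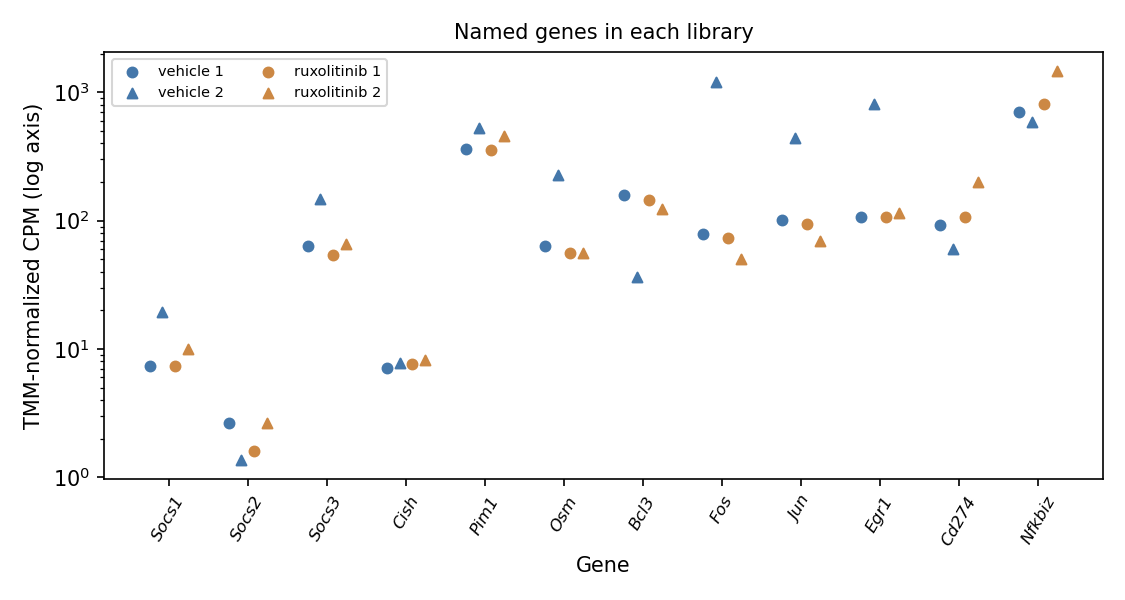
TMM-normalized CPM (counts scaled to library size; log axis) of JAK-STAT feedback genes, immediate early genes and other named genes in each of the 4 libraries; blue marks vehicle, orange ruxolitinib, circles replicate 1 and triangles replicate 2. For Fos, vehicle 2 lies at 1214 CPM and the other libraries between 49.9 and 79.1 CPM, while for Cish all 4 libraries lie between 7.11 and 8.24 CPM.

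The type I interferon-stimulated genes were lower with ruxolitinib as a list, with a median log2 fold change of -0.34 over 58 tested members, 50 of them below 0 (camera adjusted p = 2.8e-05; adjusted p = 0.80 with an estimated correlation). No single member passed the threshold, adjusted over all genes or adjusted over the list alone. Cmpk2, a mitochondrial nucleotide kinase gene induced by interferon, was at 40.4 and 121 CPM with vehicle and at 41.0 and 43.1 CPM with ruxolitinib, and Herc6, a ubiquitin ligase gene, at 7.81 and 19.2 CPM against 6.11 and 6.03 CPM. Cxcl10, a chemokine gene, went the other way, at 27.8 and 11 CPM against 29.4 and 35.1 CPM. The direction of the list rested on vehicle replicate 2: without that library the median was 0.06 (adjusted p = 0.723), and without vehicle replicate 1 it was -0.59. The interferon-gamma and antigen presentation genes had a median of 0.07 over 39 tested members (camera adjusted p = 0.217; adjusted p = 0.80 with an estimated correlation), with 0 calls. The list passed at the preset correlation without vehicle replicate 2 (median 0.13, adjusted p = 0.0175) and without ruxolitinib replicate 1 (0.22, adjusted p = 0.000963), and its median was -0.04 without ruxolitinib replicate 2 and -0.02 after removal of the gene length trend, an alternative chosen after the data were seen. In that list Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29362107 to 29388095), was at 92.9 and 60.4 CPM with vehicle and at 108 and 201 CPM with ruxolitinib, a log2 fold change of 1.01 ± 0.36.

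The NF-kB targets, cytokines and chemokines were higher with ruxolitinib as a list, with a median log2 fold change of 0.45 over 50 tested members, 41 of them above 0 (camera adjusted p = 2.3e-09; adjusted p = 0.80 with an estimated correlation). With each library left out in turn the medians ranged from 0.14 without vehicle replicate 2 to 0.97 without vehicle replicate 1. These fits share libraries and are not separate support. The size of the rise rested on vehicle replicate 2, where the list lay at a median log2 of -0.80 against vehicle replicate 1. No member passed the threshold by itself, adjusted over all genes or adjusted over the list alone. Nfkbiz, which encodes the nuclear regulator IkB-zeta, was at 701 and 589 CPM with vehicle and at 818 and 1469 CPM with ruxolitinib, a log2 fold change of 0.83 ± 0.32 (SE, n = 2 per group). Rel, an NF-kB subunit gene, was at 168 and 98.1 CPM against 195 and 259 CPM. The neutrophil-attracting chemokine gene Cxcl2 went the other way, at 249 and 754 CPM against 239 and 252 CPM. Between ruxolitinib replicate 1 and vehicle replicate 1 the median of the list was -0.00, and between ruxolitinib replicate 2 and vehicle replicate 2 it was 1.02.

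The immediate early genes, which respond to stimulation within minutes, had a median log2 fold change of -0.20 over 44 tested members and did not pass the camera test (adjusted p = 0.0541; adjusted p = 0.80 with an estimated correlation). With DESeq2's statistics the list passed (adjusted p = 0.000672). Fos had a log2 fold change of -3.40 ± 0.88 (SE, n = 2 per group; edgeR adjusted p = 0.975), Jun, the partner of Fos in AP-1, one of -1.71 ± 0.53, and the transcription factor gene Egr1 one of -2.06 ± 0.66. Egr1 was at 108 and 812 CPM with vehicle and at 106 and 115 CPM with ruxolitinib. Nr4a2, an orphan nuclear receptor gene, went the other way, at 8.32 and 5.80 CPM against 12.4 and 17.4 CPM. Fos passed the threshold without vehicle replicate 1 (log2 fold change -4.29), without ruxolitinib replicate 1 (-3.68) and without ruxolitinib replicate 2 (-3.14), and so did Egr1 (-2.87, -1.99 and -2.11), while Jun passed without vehicle replicate 1 (-2.40). The list passed camera at the preset correlation in the same 3 fits as Fos (medians -0.39, -0.27 and -0.26). Without vehicle replicate 2 its median was -0.00 (adjusted p = 0.599). The heat shock genes Hspa1b and Hspa1a were likewise highest in vehicle replicate 2, Hspa1b at 2.48 and 21.0 CPM with vehicle and 1.53 and 2.43 CPM with ruxolitinib, and Hspa1b passed the threshold without vehicle replicate 1 (-3.40) and without ruxolitinib replicate 2 (-2.93), Hspa1a without vehicle replicate 1 (-2.81). The stress, heat shock and unfolded protein response genes as a list had a median of 0.04 over 37 members, a mean of -0.12 and no camera call (adjusted p = 0.813).

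By the fixed rule for naming genes, the 5 smallest p-values among genes higher with ruxolitinib belonged to Cd274, Impact, Clk1, Nfkbiz and Slco4a1, and the 5 among genes lower belonged to Fos, Jun, Osm, Sgk1 and Gadd45g, none past the threshold. Clk1, which encodes a kinase of splicing factors, was at 395 and 205 CPM with vehicle and at 427 and 842 CPM with ruxolitinib. Impact, a regulator of translation under stress, was at 70.4 and 32.2 CPM against 86.7 and 127 CPM. Sgk1, a kinase gene of the AGC family, was at 97.1 and 307 CPM against 91.3 and 74.6 CPM.

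The lists that describe the neutrophil itself were not called by camera, which does not show that they were unchanged. Granule protein genes had a median log2 fold change of -0.00 over 36 members (camera adjusted p = 0.948). Neutrophil surface, maturity and migration genes had a median of -0.01 and a mean of 0.01 over 42 members (adjusted p = 0.813). NADPH oxidase and extracellular trap genes had a median of -0.11 (adjusted p = 0.692), and neutrophil transcription factor genes one of -0.04 (adjusted p = 0.807). Apoptosis and survival genes had a median of 0.05 (adjusted p = 0.439), glycolysis and hypoxia genes -0.05 (adjusted p = 0.655), and cholesterol and fatty acid synthesis genes 0.11 (adjusted p = 0.131). Each of these lists held 0 calls, adjusted over all genes or adjusted over the list alone. Icam1, the adhesion molecule gene, was at 168 and 43.0 CPM with vehicle and at 185 and 250 CPM with ruxolitinib, and Cxcr2, the main chemokine receptor gene of neutrophils, at 526 and 1036 CPM against 542 and 463 CPM. The survival gene Bcl2a1b was at 40.4 and 9.07 CPM against 47.1 and 67.9 CPM, with the caution that near-identical paralogs of this gene can share reads.

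The cell cycle genes were lower with ruxolitinib as a list, with a median log2 fold change of -0.19 over 46 members (camera adjusted p = 0.0345; adjusted p = 0.80 with an estimated correlation). Plk1, a mitotic kinase gene, was at 17.1 and 23.5 CPM with vehicle and 16.1 and 7.57 CPM with ruxolitinib, and Cenpf, a kinetochore gene, at 16.8 and 28.5 CPM against 17.7 and 8.16 CPM. The call was lost without ruxolitinib replicate 2 (median -0.01, adjusted p = 0.974) and without vehicle replicate 1 (median -0.25, adjusted p = 0.263), with DESeq2 (adjusted p = 0.0694), and when genes with 1 count in any library were kept (adjusted p = 0.103), and the median was -0.31 without ruxolitinib replicate 1.

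Markers of other marrow cells differed between single libraries. Eosinophil, basophil and mast cell markers were lower with ruxolitinib as a list, with a median of -0.51 over 19 members (camera adjusted p = 0.000161; adjusted p = 0.80 with an estimated correlation). Prg2, which encodes a granule protein of eosinophils, was at 489 and 681 CPM with vehicle and 563 and 208 CPM with ruxolitinib, and the list was at -0.17 without ruxolitinib replicate 2 (adjusted p = 0.486) and at -0.84 without ruxolitinib replicate 1. Dendritic cell markers were higher as a list, with a median of 0.25 over 19 members (camera adjusted p = 0.0345; adjusted p = 0.80 with an estimated correlation). The call was lost without vehicle replicate 1 (median 0.43, adjusted p = 0.113), without vehicle replicate 2 (0.10, adjusted p = 0.55), without ruxolitinib replicate 2 (0.08, adjusted p = 0.486) and when genes with 1 count in any library were kept (0.26, adjusted p = 0.0713). Cd74, the invariant chain of MHC class II, was at 2354 and 1875 CPM with vehicle and 2220 and 3836 CPM with ruxolitinib. Of the 20 measured dendritic cell markers, 8 are in another list, so the call is not specific to these cells. Erythroid markers had a median of 0.13 (adjusted p = 0.0581), B lineage markers 0.16 (adjusted p = 0.15), T and natural killer cell markers 0.13 (adjusted p = 0.374) and monocyte and macrophage markers -0.30 (adjusted p = 0.15), each at an adjusted p of 0.80 with an estimated correlation. At the preset correlation the erythroid markers passed without ruxolitinib replicate 1 (median 0.40, adjusted p = 5.8e-09), without vehicle replicate 2 (0.24, adjusted p = 7.4e-06), with DESeq2 (0.13, adjusted p = 0.00487) and when genes with 1 count in any library were kept (0.16, adjusted p = 0.0353), and their median was -0.08 without ruxolitinib replicate 2. The B lineage markers passed without ruxolitinib replicate 1 (0.38, adjusted p = 0.000963) and without vehicle replicate 2 (0.24, adjusted p = 2.9e-05), and were at -0.09 without ruxolitinib replicate 2. The monocyte and macrophage markers passed without vehicle replicate 1 (-0.60, adjusted p = 0.0478) and were at 0.03 without vehicle replicate 2. Megakaryocyte and platelet markers were at -0.09 (adjusted p = 0.763), stem and progenitor cell markers at -0.22 (adjusted p = 0.217) and stromal and endothelial markers at -0.02 (adjusted p = 0.807). Globin genes made up 2.16% of the counts in ruxolitinib replicate 2 and between 0.868% and 0.912% in the other libraries.

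All 79 tested cytosolic ribosomal protein genes had a log2 fold change above 0, with a median of 0.46 (camera adjusted p = 1.8e-18; adjusted p = 0.80 with an estimated correlation), and none passed the threshold by itself. Rps9 was at 597 and 581 CPM with vehicle and at 612 and 962 CPM with ruxolitinib, and Rpl4 at 543 and 505 CPM against 528 and 797 CPM. These genes made up 2.66% of the counts in ruxolitinib replicate 2 and between 1.53% and 1.69% in the other libraries. Without ruxolitinib replicate 2 the median was 0.03 (adjusted p = 0.762), and without ruxolitinib replicate 1 it was 0.81. Removing each library's gene length trend, chosen after the data were seen, lowered the median to 0.21 (adjusted p = 2.1e-07).

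**Figure D3:**
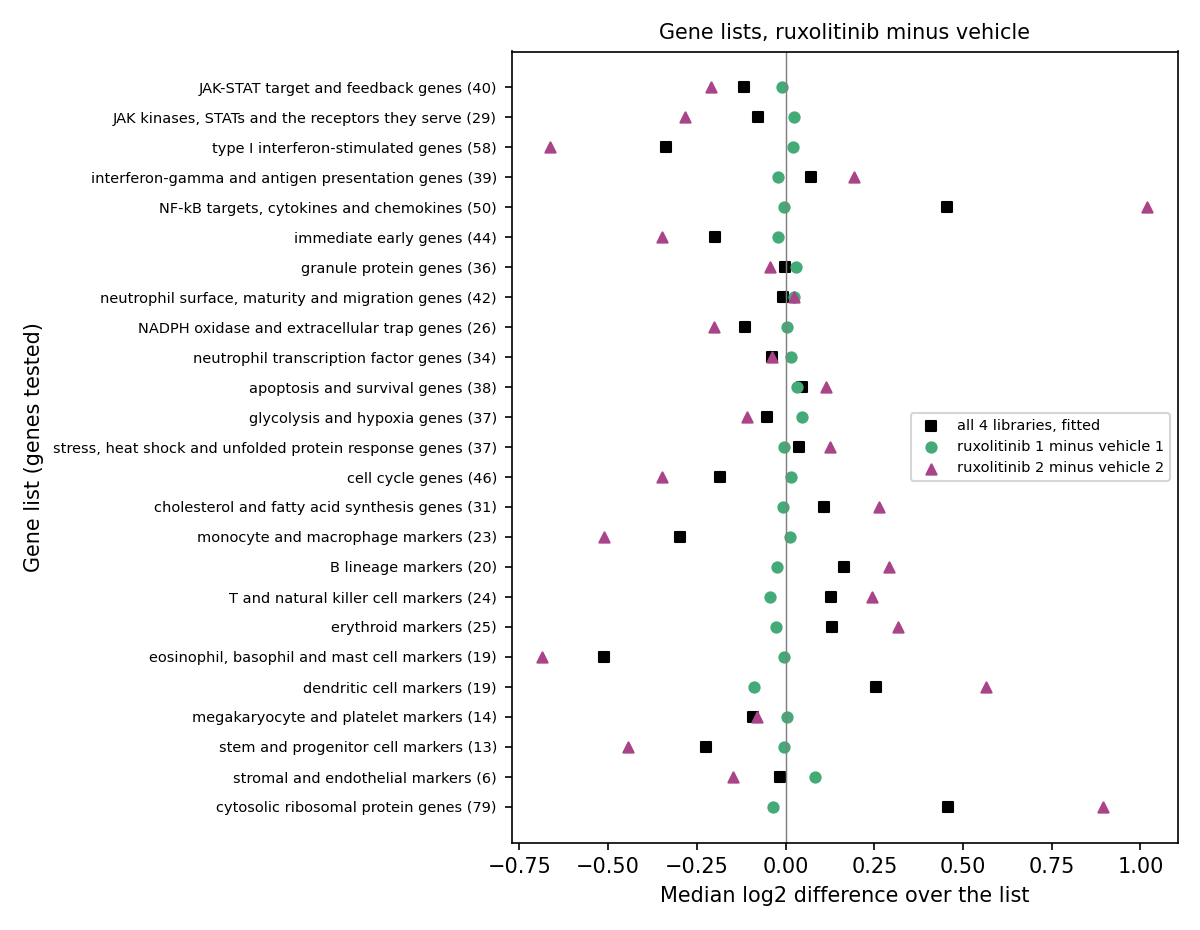
Median log2 difference, ruxolitinib minus vehicle, over the tested genes of each list; black squares are the fit to all 4 libraries, green circles ruxolitinib 1 minus vehicle 1 and purple triangles ruxolitinib 2 minus vehicle 2. For the NF-kB targets the circle lies at -0.00 and the triangle at 1.02.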

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

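The removal of the gene length trend was chosen after the data were seen. The counts of 0 genes higher and 0 genes lower with ruxolitinib were the same under RLE scaling, both other filters, DESeq2, limma-voom, a fold change of at least 2, an adjusted p below 0.1 and the length correction. The replicate number as a block gave 9 genes higher and 7 lower, Fos, Acod1 and Csf1 among them. Nothing states whether same-numbered libraries share a preparation. Their deviations from the group means correlated at 0.04. That correlation does not exclude a shared source for vehicle replicate 1 and ruxolitinib replicate 1, the closest pair (BCV 3.63%). Leaving out each library gave 1 to 853 genes higher and 1 to 792 lower, the highest counts without vehicle replicate 1, where a lone vehicle library is assumed to vary like the ruxolitinib libraries. The number of lists called by camera, 6, ranged from 3 to 10 when a library was left out and was 0 with an estimated correlation, which leaves medians as they are (-0.34 for interferon-stimulated genes, 0.45 for NF-kB targets, -0.19 for cell cycle genes, -0.51 for eosinophil, basophil and mast cell markers, 0.25 for dendritic cell markers and 0.46 for ribosomal protein genes) and put all 6 lists at an adjusted p of 0.80. It takes correlations of 0.16 to 0.96 for these lists in place of 0.01, and a t distribution with 2 degrees of freedom, whose shares were not separated.

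Without vehicle replicate 2 the type I interferon-stimulated genes changed direction (0.056), and their medians ranged from -0.59 to 0.056 over the left-out libraries. The ranges were -0.20 to 0.024 for the JAK-STAT target and feedback genes, -0.31 to -0.0062 for cell cycle genes, -0.84 to -0.17 for eosinophil, basophil and mast cell markers, 0.081 to 0.43 for dendritic cell markers and 0.034 to 0.81 for ribosomal protein genes. The cell cycle genes lost their call with the filter of 1 count (-0.18) and with DESeq2 (-0.19), and the dendritic cell markers with the filter of 1 count (0.26); the cause was not tested. By the direction of the camera statistic, which can differ from the sign of the median, the other lists kept their direction and their side of the threshold in 197 combinations of list and alternative, newly passed the threshold in 15, and changed direction without a call in 22. The block newly called immediate early genes (-0.20) and erythroid markers (0.10). By the sign of the log2 fold change, the named genes gave 954, 64 and 35 such combinations, with 62 of the 64 new calls when a library was left out. Depth limits genes of few counts: Socs2 had below 3 CPM.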

Other observations

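Set against the ruxolitinib libraries by itself, vehicle replicate 2 was lower in part of the NF-kB targets and higher in part of the immediate early and interferon-stimulated genes. No list passed with an estimated correlation in that fit, and examples were chosen after their values were seen. Against vehicle replicate 1, monocyte and macrophage markers were at a median log2 of 0.54 and dendritic cell markers at -0.38. The other lists of other cells lay between -0.01 (eosinophil, basophil and mast cell markers) and 0.46 (stromal and endothelial markers, 6 tested). Whether other cells differed between the vehicle libraries was not tested. Of 50 tested NF-kB targets, cytokines and chemokines, 25 were higher and 3 lower in the ruxolitinib libraries (edgeR, without vehicle replicate 1). Traf1, an adaptor of tumour necrosis factor receptors, had 1260 counts in vehicle replicate 1, 115 in vehicle replicate 2, 1193 in ruxolitinib replicate 1 and 944 in ruxolitinib replicate 2. Acod1, which encodes the enzyme that makes itaconate, had 43356, 4224, 43107 and 41165 counts, and Csf1, the macrophage growth factor gene, 9064, 1047, 9233 and 9432. In the same list Tnf, the tumour necrosis factor gene, had 4378, 3901, 4598 and 5220 counts, and Il1b, which encodes interleukin 1 beta, 14565, 23335, 14476 and 21742. Of 45 immediate early genes, 16 were lower and 5 higher in the ruxolitinib libraries, and Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, had 12376, 37635, 10669 and 10121 counts. Of 62 type I interferon-stimulated genes, 18 were lower and 2 higher, while Isg15, which encodes a ubiquitin-like protein, had 348, 357, 287 and 369 counts. The 36 granule protein genes lay at a median log2 of 0.13 in vehicle replicate 2 against vehicle replicate 1 (quartiles -0.00 and 0.26). In vehicle replicates 1 and 2, Ngp was at 30766 and 30667 CPM and Mmp25, another granule list member, at 312 and 510 CPM.

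Ruxolitinib replicate 2 differed from ruxolitinib replicate 1 as well, by a median log2 of 0.29 over the NF-kB targets, 0.32 over the interferon-gamma and antigen presentation genes and 0.18 over the JAK-STAT target and feedback genes. Hbb-bs, a beta-globin gene, had 120412 counts against 50738, and Epx, the eosinophil peroxidase gene, 560 against 3248. The median log2 difference was 0.51 for B lineage markers and 0.54 for erythroid markers, and -0.57 for eosinophil, basophil and mast cell markers. Across genes, which are not independent replicates, the log2 ratios of ruxolitinib replicate 1 to vehicle replicate 1 and of ruxolitinib replicate 2 to vehicle replicate 2 correlated at -0.04 over all 11611 genes and at -0.22 over the 1034 genes with at least 200 CPM.

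The tests of explanations were chosen after these or closely related results had been seen; for gene length on the closest pair of libraries, the bounds were set before its result. The first pattern is how close vehicle replicate 1 and ruxolitinib replicate 1 lie. The same reads deposited under both labels are argued against, since 627 tested genes with enough counts (5.46%) differed beyond counting noise. The count of 591 took untested genes too and scaled within the pair. A simulated pair with counting noise alone gave 0 such genes, but it held neither a gene length trend nor reads shared among similar genes. One library or RNA sample sequenced under both labels therefore stays open. The differences between these libraries followed gene length in part: removing each library's length trend left 57.1% of the 627 genes, 358, and added 88 others, 446 in all. That share lies between the bounds set for and against length as the source, so the test does not decide. The fitted length trend did not account for the genes that still differed, and their source was not settled. JAK inhibition as a source also stays open, because the JAK-STAT target and feedback genes then lay at percentile 11.8 of random lists, with a median of -0.01. Whether the drug altered little within 1 h or both libraries hold cells of the same treatment cannot be told apart here, since only 1 other library per group exists.

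The second pattern is vehicle replicate 2. Ruxolitinib as its source, with the labels as given, is argued against: over the 1602 genes called between vehicle replicate 2 and the ruxolitinib libraries, vehicle replicate 1 lay at a median of 4.61% of the way from the ruxolitinib mean to vehicle replicate 2 (quartiles -7.82% and 17.3%). A lower share of neutrophils is argued against for the low NF-kB targets, because granule protein genes were at a median log2 of 0.13 between the vehicle libraries while NF-kB targets were at -0.80. A treated library labelled as vehicle replicate 1 stays open. Without that library, the JAK-STAT target and feedback genes had a median of -0.16 and a camera adjusted p of 0.22 at the preset correlation. With an estimated correlation no list passed in that fit, not even the NF-kB targets at a median of 0.97. That setting therefore cannot decide for or against a treated library. Against vehicle replicate 2, Socs3, Osm and Socs1 were lower in both ruxolitinib libraries and Bcl3 higher. Pim1 was at 527 CPM in vehicle replicate 2 against 357 and 455 CPM with ruxolitinib. Cish differed little, at 7.76 CPM against 7.57 and 8.24 CPM, so these single genes do not decide either. A hypothesis not tested here is a difference in handling between preparations; the labels give 1 h for every library and nothing on handling.

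The third pattern is the globin and ribosomal protein counts of ruxolitinib replicate 2. The differences from ruxolitinib replicate 1 followed gene length. The shortest 10% of genes lay at a median log2 of 0.40 and the longest 10% at -0.18. Whether this trend is a technical bias was not tested. Removing the trend took the ribosomal protein genes from 0.78 to 0.31 (quartiles 0.21 and 0.45), still above all random lists. The fitted trend thus did not account for all of their rise. Length bias as the whole source stays open, because the random lists were matched on abundance but not on length. A lower share of neutrophils stays open. Its test asked every list of other cells to rise, but other cell types can change separately, so it cannot decide. Medians were 0.54 for erythroid, 0.51 for B lineage, 0.38 for T and natural killer cell and 0.32 for dendritic cell markers. They were -0.57 for eosinophil, basophil and mast cell, -0.29 for stem and progenitor cell and -0.15 for monocyte and macrophage markers. More erythroid RNA is a candidate source of the globin counts, as a hypothesis. The 21 erythroid markers other than globins were at 0.43 with the length trend removed, above all random lists. Before that removal they were at 0.39, while Hbb-bs was at 1.39 and Hba-a1 at 1.27. Random lists hold unrelated genes, whereas the erythroid and ribosomal protein lists had estimated correlations of 0.65 and 0.96. The ribosomal protein list lay below all random lists even between ruxolitinib replicate 1 and vehicle replicate 1, at a median of -0.03. A place beyond all random lists therefore does not measure chance. Of the 26 measured erythroid markers, 1 is in another list, and the stated purity above 95% leaves room for other cells.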
